A study of Homo sapiens with 6 samples.

How the data were processed

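Sorted fractions of glioblastoma cell lines were profiled on 6 Affymetrix arrays. The cell lines LN229, U87MG and LN18, long-established human glioblastoma lines, were each sorted by flow cytometry with a monoclonal antibody against ABCB5, a membrane transporter of the ABC family, into an ABCB5-positive and an ABCB5-negative fraction. Each fraction of each line gave 1 array, so each of the 2 groups holds 3 arrays and each line 2. Per the labels' protocols, LN18 and LN229 were grown in DMEM and U87MG in EMEM, both with serum, total RNA was isolated with the RNeasy Plus kit, and biotinylated cRNA was hybridised.

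The deposited values are on a log2 scale. Per the submitters' processing notes, the authors used the oligo package and RMA, a method that corrects background, quantile-normalises and summarises probes; the versions, the genome build and the level of summary are not given in the sources used here. The table holds 70523 probe sets, with array medians from 4.98 to 5.13, and these log2 values were used as deposited. No scanner file was used here, so detection above background per probe could not be tested, and the number of arrays limits the precision.

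Probe sets were named from the platform annotation, with symbols updated by Entrez ID through the RefSeq gene table of GRCh38.p14. Of the probe sets, 23781 had exactly 1 gene symbol, 1543 had several and 45199 had none here; 21497 of those with 1 symbol matched by Entrez ID. A probe set with several symbols named no gene. The probe set with the highest mean over the 6 arrays stood for its gene, which gave 22465 genes. The lowest 33.3% by mean signal, 7488 genes with a mean log2 value under 5.29, was left out, and 14977 genes were tested, 12718 of them protein-coding.

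Positive and negative fractions were compared with limma 3.58.1 in R 4.3.3, with cell line and fraction as factors, an intensity trend in the empirical Bayes step, and Benjamini-Hochberg adjustment with a threshold of 0.05. The 3 contrasts between lines came from the same fit. The line was used as a block because both fractions of a pair come from the same cell line. Arrays of the same line correlated at r = 0.98 to 0.991 across genes, and arrays of different lines at 0.816 to 0.949. The labels do not say that the fractions come from repeated cultures or sorts, so p-values measure only the spread between these samples. An exact sign-flip test over 3 pairs cannot give a two-sided p below 0.25, and none was used for calls.

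Gene lists were tested with camera at its preset correlation of 0.01, two-sided, adjusted over the 39 lists with at least 5 measured members out of 40 lists of pathways and cell type markers. Camera with an estimated correlation and fry, which asks whether a set's genes move one way on balance, were run beside it. Camera with an estimated correlation rests on 2 residual degrees of freedom here. It therefore has little power, and a call lost under it leaves a list open. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes ABCB5 and a panel of 10 stem cell, drug transport and proliferation genes. It takes the 10 genes each way with the same sign in 3 lines, ranked by the smallest absolute difference with those past the threshold first. For each list past the threshold it takes the 4 members with the largest mean difference in the list's direction. These are the list's extremes, not typical members. It also takes the 5 genes per line furthest from both other lines. Sorting of short RNAs into classes by symbol and RefSeq biotype, the protein-coding and short-RNA subsets, and tests of lists between lines were chosen after seeing the data. Probe sets of some MHC region genes, HLA-DRB1 and LY6G5B among them, are placed on alternative haplotype sequences in the annotation, so their values are less certain.

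On simulated data for the positive against negative comparison, with 14977 genes and noise drawn from the fitted spread, limma recovered 72% of 50 genes changed by 0.5 log2 units. It recovered 100% of those changed by 1, 2 or -1 log2 units, and called 8 of 14777 unchanged genes. Camera called both shifted lists and 1 of 37 others. The simulated genes were independent of each other, which real genes are not. Each simulated change was also the same in the 3 lines, so the recovery does not cover changes that vary between lines. SNORA38, at 2.01 with an SD of 1.01 between lines, was not called in the real data (adjusted p = 0.0511 in limma). The alternatives were no block, leaving out each line, no filter or a stricter one at the median signal, cyclic loess, median centring, no intensity trend, robust empirical Bayes, array weights, the mean of a gene's probe sets, and all probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.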

Results

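Gene expression was measured on 6 arrays, 1 for the ABCB5-positive and 1 for the ABCB5-negative fraction of each of the glioblastoma lines LN229, U87MG and LN18. Values are log2 RMA signals, and a difference is the positive minus the negative fraction, given as the mean of 3 lines with the SD between lines. The median of the 14977 genes tested differed by -0.001 between the fractions.

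ABCB5 itself, the transporter whose protein was the basis of the sort, had a log2 signal between 2.55 and 2.66 on each of the 6 arrays, at percentile 2.66 of the genes measured. Its difference was 0.04 ± 0.04 (SD, n = 3), with a 95% confidence interval of -0.07 to 0.15 and an adjusted p of 0.845 in limma. It lay in the lowest 33.3% of genes by signal, so these values come from the fit without that filter. A signal this near the bottom of the array's range cannot show whether the transcript differed, and under cyclic loess the difference was -0.04.

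The other genes of the panel did not pass the test. SOX2, a transcription factor of neural stem cells, differed by 0.15 ± 0.26, and the neural stem cell filament gene NES by 0.16 ± 0.19. The stem cell surface genes PROM1 and CD44 differed by 0.07 ± 0.03 and -0.04 ± 0.11. MGMT, which repairs the DNA lesion made by temozolomide, differed by 0.06 ± 0.08. Among drug efflux transporters, ABCB1 differed by 0.07 ± 0.07, ABCG2 by 0.03 ± 0.15 and ABCC1 by -0.04 ± 0.14. The proliferation gene MKI67 differed by -0.13 ± 0.08 and the cell cycle inhibitor CDKN1A by -0.11 ± 0.07. Their adjusted p values in limma ranged from 0.626 to 0.948, and PROM1 and ABCB1, like ABCB5, lay in the lowest 33.3% by signal. The sign of ABCG2 turned under cyclic loess (-0.01), median centring (-0.01) and without LN18 (-0.05), and those of CD44 (0.02) and ABCC1 (0.04) without U87MG.

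**Figure D1:**
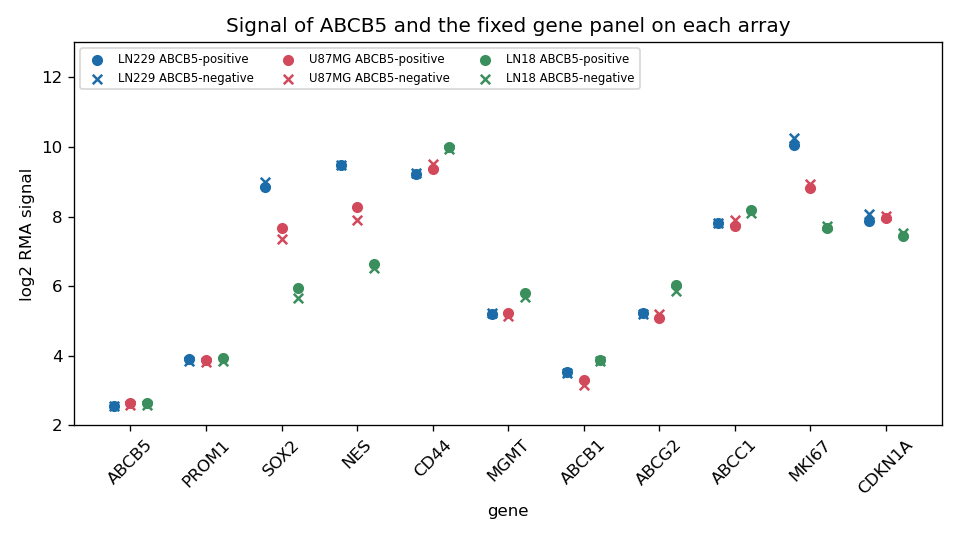
Log2 RMA signal (vertical axis) of ABCB5 and the 10 panel genes (horizontal axis) on each of the 6 arrays, circles for ABCB5-positive and crosses for ABCB5-negative fractions, coloured by line. ABCB5 lies between 2.55 and 2.66 on each array, and SOX2, NES and MKI67 are separated by line.

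Short structural noncoding RNAs made up nearly all of the genes that differed between the fractions. Of the 96 genes past the threshold, 92 rose and 4 fell in the ABCB5-positive fraction, and 90 of the 92 were small nucleolar, small Cajal body, small nuclear, 5S or Y RNA genes and their copies. The genes that rose did so by 1.29- to 5.76-fold, with a median of 1.74-fold, and 25 of them by more than 2-fold. SNORA31 and SNORD14E, guides of ribosomal RNA modification, rose by 5.76-fold (log2 2.52 ± 1.20) and 5.08-fold (2.35 ± 1.07). The small Cajal body RNAs SCARNA8, SCARNA11, SCARNA4 and SCARNA14, of the group that guides modification of spliceosomal RNAs, rose by 5-, 4.53-, 4.5- and 4.49-fold, with SDs between lines of 0.65, 0.50, 0.81 and 0.43 log2 units.

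SCARNA27, a small Cajal body RNA, rose by 1.59 ± 0.01 log2 units (adjusted p = 0.000155 in limma), RNU5E-4P, a U5-like copy, by 1.64 ± 0.23 and SNORD1B, a snoRNA, by 2.84-fold (SD 0.16 log2 units). SNORA65 rose by 1.56 ± 0.46. The 96 genes had the same sign in each of the 3 lines, and of the 92 with a RefSeq length, 87 were shorter than 200 nt. Of the 90 short RNAs 52 have a pseudogene symbol, and among the short RNA genes tested 13 pairs had identical values, so those pairs were not measured apart. Probe sequences were not used, so whether other copies share signal with each other or with a parent RNA was not tested. Counts of copies may therefore not be counts of separate RNAs. Without LN229 the 1 gene called was SCARNA27. Without U87MG, SNORA31, SNORD14E, SCARNA4, SCARNA8 and RNU11 missed the threshold, with differences of 2.35, 2.34, 2.04, 2.27 and 1.44, as did the 4 genes that fell. SNORA31, SNORD14E and SCARNA4 also missed it without the filter, under cyclic loess and under median centring, with SNORA31 at 2.53 under loess, and SNORA31 and SNORD14E without an intensity trend.

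By class, 26 of 134 snoRNAs tested rose, with median differences of 0.61 in LN229, 0.81 in U87MG and 0.14 in LN18. Of 20 scaRNAs 6 rose, with medians of 0.63, 0.90 and 0.02. The 205 5S-like genes, 35 of which rose, had medians of 0.24, 0.40 and 0.41. Of 9 U5-like copies 7 rose, with medians of 0.92, 0.77 and 0.76, and of 12 U1-like copies 8, with medians of 0.82, 0.99 and 0.59. Of 50 U6-like genes 4 rose, with medians of 1.16, 0.72 and 0.23, of 10 Y-like genes 2 and of 31 other small nuclear RNA genes 2, the last with a median of -0.05 in LN18. The 23 groups of background probes on the array, sorted by GC content, also lay higher in the positive fractions in the mean of the lines, with median shifts of 0.09 in LN229, 0.16 in U87MG and 0.11 in LN18, where 2 groups lay lower (-0.02 and -0.06). Camera on these classes gave adjusted p = 0.119 to 0.31 with an estimated correlation, so it did not repeat the class calls made at the preset correlation. With 2 residual degrees of freedom that version has little power, so its result settles nothing either way. The U1- and U5-like classes, higher in each line in 100% of genes, gave 0.211 and 0.119 there.

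**Figure D2:**
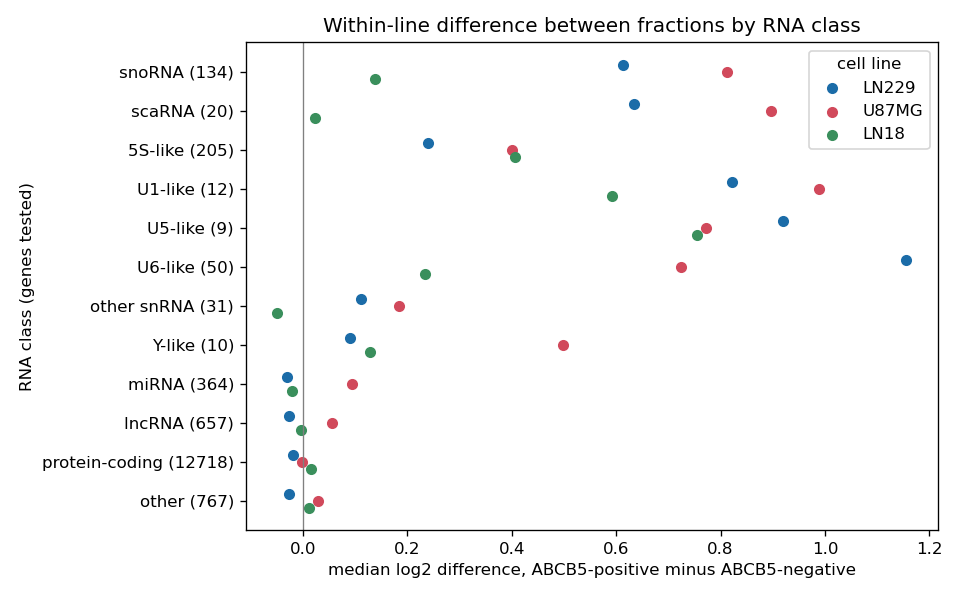
Median log2 difference between ABCB5-positive and ABCB5-negative fractions (horizontal axis) of the genes of each RNA class (vertical axis, genes tested in parentheses), 1 point per line. Protein-coding medians lie between -0.02 and 0.02, and the U5-like medians between 0.76 and 0.92.

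Outside the classes of short RNAs set by symbol, 2 genes rose and 4 fell. OR2G3, an olfactory receptor gene named after its value was seen, rose by 0.44 ± 0.07, and the other was a copy of the 5.8S ribosomal RNA gene, itself short, which the classes did not cover. The microRNA genes MIR4521 and MIR221 fell by 0.76 and 0.64 on the log2 scale, the long noncoding RNA LINC00294 by 0.46 and LY6G5B, a gene of the MHC region, by 0.69 (changes of -0.76 ± 0.25, -0.64 ± 0.18, -0.46 ± 0.13 and -0.69 ± 0.26). Lower in the 3 lines but not past the threshold were BACE1-AS (-0.67 ± 0.30), NPIPB11 (-0.52 ± 0.27), MT1CP (-0.56 ± 0.21), UBR1 (-0.40 ± 0.08), MIR548H3 (-0.39 ± 0.14) and MT2A (-0.38 ± 0.09). BACE1-AS, MT1CP and UBR1 passed with the stricter filter, with array weights and without LN18. With the 12718 protein-coding genes tested alone, limma called 0, with a lowest adjusted p of 0.32 and 1152 genes at an unadjusted p under 0.05, where 636 would be expected by chance, so the calls of OR2G3 and LY6G5B ended. Their largest mean changes were 1.39-fold higher and 1.69-fold lower.

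The count of 96 and its balance of 92 higher and 4 lower depended strongly on the fit, and at an unadjusted p under 0.05 there were 733 higher and 798 lower genes. Without the line as a block limma called 0 genes (157 at an unadjusted p under 0.05, lowest adjusted p = 1), and with all probe sets tested 5; without LN229 it called 1, without U87MG 20 and without LN18 1092 (457 higher, 635 lower), the last with an infinite prior degrees of freedom, so that one trend stood for the spread of each gene. No filter gave 42, cyclic loess 38 and median centring 36, each with 0 lower, so that the calls of LY6G5B, MIR4521, MIR221 and LINC00294 ended there. Array weights gave 8 lower and no trend 2.

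**Figure D3:**
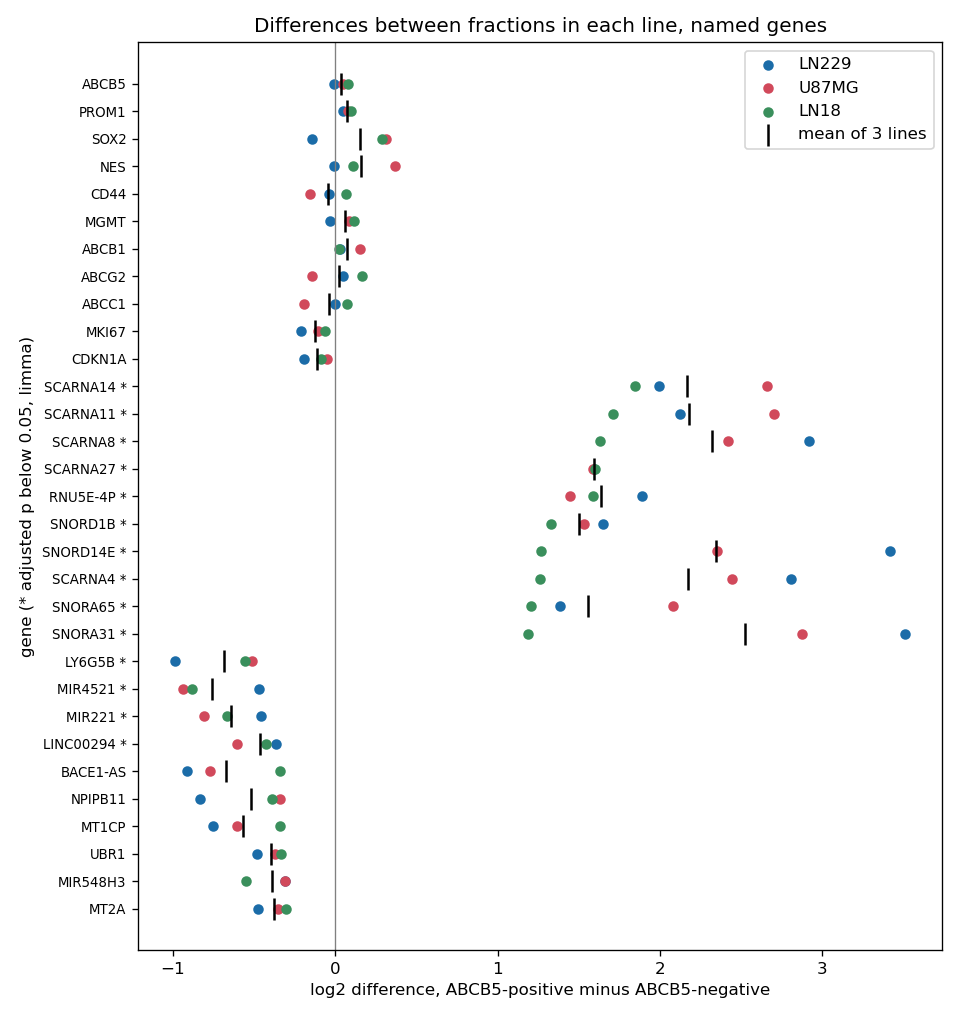
Log2 difference between ABCB5-positive and ABCB5-negative fractions (horizontal axis) of ABCB5, the panel and the 10 named genes each way (vertical axis), 1 point per line and a bar for the mean, asterisks for an adjusted p below 0.05 in limma. ABCB5 lies near 0, and SCARNA27 has an SD of 0.01 between lines.

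Lists past the threshold numbered 4: these passed camera at the preset correlation, 2 higher and 2 lower. The list of small nucleolar and small nuclear RNA genes rose (adjusted p = 5.36e-17; adjusted p = 0.921 with an estimated correlation). Of its 34 members tested 6 rose over all genes and 18 when adjusted over the list alone, with a median of 0.47 and medians of 0.64 in LN229, 0.88 in U87MG and 0.04 in LN18. RNU11, a minor spliceosome RNA, rose by 1.58 ± 0.36, while SNORA38, at 2.01 ± 1.01, did not pass over all genes. The list of cytosolic ribosomal proteins was higher (adjusted p = 0.00757; adjusted p = 0.921 with an estimated correlation), with 0 of 48 members past the threshold over all genes and 0 adjusted over the list alone. Of the members 36 were higher and 12 lower, the median was 0.07, and RPS25, RPL27, RPL10A and RPS14 differed by 0.21 ± 0.15, 0.20 ± 0.21, 0.20 ± 0.12 and 0.17 ± 0.18. The call ended without LN229 (0.285), without LN18 (0.0872) and without the line as a block (0.434).

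The mesenchymal glioblastoma list was lower (adjusted p = 0.00794; adjusted p = 0.921 with an estimated correlation), with 0 of 26 members past the threshold over all genes and 0 adjusted over the list alone. Of the members 24 were lower and 2 higher, and the medians were -0.05 in LN229, -0.27 in U87MG and 0.05 in LN18. S100A11, CHI3L1, TNFRSF1A and LGALS1 differed by -0.39 ± 0.33, -0.36 ± 0.46, -0.20 ± 0.17 and -0.19 ± 0.18. The call ended without U87MG (0.966) and without the line as a block (0.238). The MHC and antigen processing list was lower too (adjusted p = 0.008; adjusted p = 0.921 with an estimated correlation), with 0 of 25 members past the threshold either way of adjusting, over all genes or adjusted over the list alone. Of the members 18 were lower and 7 higher, with medians of -0.08, -0.18 and 0.03. The class II genes HLA-DRB1, HLA-DMA, HLA-DPA1 and CD74 differed by -0.52 ± 0.33, -0.38 ± 0.33, -0.26 ± 0.24 and -0.24 ± 0.32. This call too ended without U87MG (0.479) and without the line as a block (0.436). Without LN229 camera called 12 lists, without the filter 9 and without the line as a block 1.

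The other lists did not pass, with adjusted p from 0.0536 to 0.993. Collagens and matrix, median 0.04, and lysosome and autophagy, median -0.06, lay nearest to the threshold at 0.0536 each. Apart from XRCC2 and H2BC14, named after their values were seen, no member of these lists passed over all genes or adjusted over the list alone. In the DNA repair list XRCC2, at -0.32, passed when adjusted over the list alone and not over all genes (adjusted p = 0.0787 in limma), and in the replication histone list H2BC14, at -0.49, did likewise (0.164). The marker lists of other cell types had adjusted p of 0.183 for neurons, 0.274 for melanocytes, 0.494 for astrocytes, 0.546 for epithelium, 0.87 for endothelium and pericytes, and 0.969 for oligodendrocytes and for immune cells. Median and mean differed in sign for endothelium (0.02 and -0.002), oligodendrocytes (0.01 and -0.01), immune cells (0.001 and -0.02) and oxidative phosphorylation (0.01 and -0.02), which camera placed up, and for cholesterol synthesis (0.003 and -0.01), which it placed down. Fry called 0 lists, with 0 at an unadjusted p under 0.05, and camera with an estimated correlation 0, also with 0 at an unadjusted p under 0.05. Fry for changes either way called 0, with 5 at an unadjusted p under 0.05, where camera at the preset correlation had 10.

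The differences of short RNAs correlated more between the lines than those of protein-coding genes, a contrast that was not tested. Across the genes tested, which are not independent replicates, the differences correlated at r = 0.56 for LN229 with U87MG, 0.345 for LN229 with LN18 and 0.28 for U87MG with LN18. Across protein-coding genes r was 0.313, 0.1 and 0.057, and across the 471 short noncoding RNAs 0.796, 0.46 and 0.487. Spearman rho over the genes tested was 0.277, 0.131 and 0.115. In 55 genes the positive fraction was more than 1.5-fold higher in each line, and these 55 were short noncoding RNA genes; 0 genes were lower by as much. The same sign in 3 lines was seen in 31% of genes, and 25% would share it by chance.

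Beyond 2-fold, 109 genes were higher in the positive fraction of LN229, 68 in that of U87MG and 32 in that of LN18, and protein-coding genes numbered 0 among them in each line. Lower by more than 2-fold were 2 genes in LN229, 10 in U87MG and 0 in LN18, where 5 were lower without the filter. In LN229 these were SNAI1, a regulator of epithelial-mesenchymal transition (2.28-fold), and ZFP36, an mRNA decay factor (2.17-fold). In U87MG 9 were protein-coding, among them ULBP1, a ligand of the NK cell receptor NKG2D (2.65-fold), and GABRQ (2.24-fold). ZFP36 was lower there beyond 2-fold too, at -1.037 log2 units. These 4 genes were named after their values were seen. One array stands behind each fraction of a line, so these within-line differences have no test.

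The lines differed far more than the fractions did. In limma 3916 genes differed between LN229 and U87MG, 7546 between LN229 and LN18 and 7390 between U87MG and LN18, of which 72, 324 and 273 differed by more than 4-fold. U87MG was grown in EMEM and LN229 and LN18 in DMEM, so contrasts with U87MG cannot separate line from medium. The genes named for each line had adjusted p values from 1.16e-07 to 0.000191. CCL2, a monocyte chemokine, was higher in LN229 than in both other lines by at least 10.3-fold and EFEMP1, a matrix glycoprotein, by at least 9.24-fold. COL6A3, EREG and LOX were lower there by at least 10.9-, 9.75- and 9.41-fold. In U87MG the cytokine gene IL36B was higher by at least 153-fold, ADCY8 by at least 9.83-fold, SBSN by 8.99-fold, the carbonic anhydrase gene CA12 by 8.68-fold and the cholesterol exporter ABCA1 by 8.56-fold. LN18 had at least 75.6-fold more GTSF1 and 33.9-fold more OLR1, and less of the class II gene HLA-DRA by at least 41.6-fold, HMCN1 by 34.8-fold and FREM2 by 27.5-fold.

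Of the panel, SOX2, NES and MKI67 were highest in LN229 and lowest in LN18, with mean log2 signals of 8.93, 7.50 and 5.79 for SOX2, 9.48, 8.08 and 6.58 for NES, and 10.15, 8.89 and 7.70 for MKI67 in LN229, U87MG and LN18. MGMT was higher in LN18, at 5.75 against 5.23 and 5.19, as was ABCG2, at 5.94 against 5.21 and 5.14. The differences between lines correlated between the positive and negative fractions at r = 0.882 to 0.951 across genes. The 2 fractions are the only samples of a line, and with fraction in the fit these p-values take as the error how far the fraction difference varied between lines, which does not cover the spread between cultures.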

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

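The gap between lines, the tests of short-RNA recovery and of background as the whole cause, and the deciding test for ribosomal genes were chosen after the results were seen. Values with opposite signs in different lines and a gap of at least 0.3 log2 units are given here, and the differences between lines were not tested, because each line has 1 pair of arrays. SOX2 differed by -0.14 in LN229 and by 0.32 and 0.29 in U87MG and LN18, a gap of 0.46. For NES the gap was 0.38, with LN229 lowest at -0.005, and for ABCG2 0.31, with U87MG lowest at -0.14. Lower in U87MG and higher in LN18 were ULBP1 (gap 1.605) and GABRQ (1.239, with 0.076 in LN18). CD74 (gap 0.634), HLA-DPA1 (0.45) and TNFRSF1A (0.321) were lower in LN229 and in U87MG. In LN18 they differed by only 0.086, 0.014 and 0.002, which shows no clear rise there. RPL27 (0.427) and RPS14 (0.327) were lower in LN18 alone, at only -0.001 and -0.029. The median of the mesenchymal glioblastoma list ran from -0.27 in U87MG to 0.05 in LN18, a gap of 0.32. Among the 25131 probe sets with no gene name here, 1 passed the threshold when all probe sets were tested, higher in the positive fraction.

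Short RNAs were higher in the positive fractions. For snoRNAs and scaRNAs, a matching rise in the measured RNA of the genes that hold them is argued against. The 69 measured genes that contain 1 of 81 such RNAs, with no selection on sign, had a median difference of -0.038. Its SE was 0.015 across genes, which are not independent, and the RNAs themselves had 0.662. The 61 genes that contain an RNA with a difference above 0, past the threshold or not, had -0.028. Strand was not used, transcription itself was not measured, and the other short classes were not covered. For the 471 short RNAs pooled, a background or GC shift as the whole cause is argued against too. Their median exceeded the largest shift of a background GC group in the same line by 0.135 ± 0.039 (SD, 3 lines). Medians of 5S-, U1-, U5- and U6-like genes lay above that largest shift in each line. In LN18 the medians of snoRNAs (0.139), scaRNAs (0.023) and Y-like genes (0.128) lay below it (0.195). The median of other small nuclear RNAs lay below it in each line, and that of Y-like genes also in LN229 (0.091 against 0.207). For these classes in those lines the test does not decide, and background as the whole cause stays open. With a median background shift of 0.116, a part of the rise stays open to such a shift. Unequal recovery of short RNA between fractions may account for the rise. In that test 7 classes lay above protein-coding genes in each line, though scaRNAs in LN18 barely did, at 0.023 against 0.015. The class of other small nuclear RNAs, not part of that test, had -0.049 in LN18. Medians of noncoding RNAs other than miRNA genes fell with length, from 0.384 for the 433 under 200 nt. They were 0.227, 0.033 and 0 for the 41, 183 and 1093 in classes of rising length. RN7SK and RN7SL1 moved by 0.088 and 0.078. With RMRP, RPPH1 and TERC the median of the longer structural RNAs was 0.239. That lies over the limit of 0.205 set for unequal recovery, so this explanation stays open. The 364 miRNA genes, annotated as short too, had 0.016. Which RNA their probe sets detect was not tested, so they do not decide the question. A real difference between ABCB5-positive and ABCB5-negative cells is confounded with whatever the sort or isolation did to each fraction, and remains open and untested.

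The ribosomal protein list rose at the preset correlation, and snoRNA signal inside ribosomal protein genes could have produced that. The 42 genes with no snoRNA inside had a median of 0.08 ± 0.02 (SE), which argues against it as the whole cause, and the 6 with one had 0.02 ± 0.08. The difference of -0.06 ± 0.08 (SE) between them, the test written beforehand, settled nothing. A further 20 members share a probe set with another symbol and were not measured. With the call lost under an estimated correlation, whether the list differs at all stays open.

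LN229 and U87MG arrays correlated with each other more than either did with LN18. LN229 cells in the U87MG samples or the reverse were weighed as a cause. Genes bright in LN229 and more than 3.5 log2 units lower in U87MG numbered 0, with CCL2 nearest at 10.3-fold, which leaves LN229 cells in the U87MG samples open. In the reverse direction there were 5. IL36B, EREG, CA12, COL6A3 and CHI3L1 were lower in LN229 than in U87MG by 193-, 18.9-, 12.9-, 11.9- and 11.6-fold. IL36B and EREG lay under the filter limit of 5.29 in LN229. These 5 genes argue against a large share of U87MG cells in the LN229 samples, and a small share stays open. The rule set beforehand asked for 5 such genes in both directions, so it did not settle the matter. A biological likeness of the lines stays open and was not tested.

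The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 96 genes and the highest other 0, and 1 split of the 10, the real one, gave as many. With the line as a block, every other split rests on the pair of 1 line or turns the sign in 1 line. Both lower the count of genes, so the 0 does not show what chance would give. For gene lists the real split gave 4 and the highest other 13, and 6 of the 10 gave at least 4. Among the 4 splits that part the 3 pairs, the others, which turn the sign of the difference in 1 line, gave 7, 10 and 13 lists. These list counts come from camera at the preset correlation, with which the real split's calls were lost under an estimated one. Whether counts above the real one reflect line-specific differences between fractions or that preset value was not tested.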

How the results depend on the processing

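The settings with protein-coding genes alone and with short classes left out were chosen after seeing the data. Counts against the reference setting of 96 genes (92 higher, 4 lower) and 4 lists follow; the cause of each change was not tested unless named. Without the replicate block limma called 0 genes (0 higher, 0 lower) and camera 1 list, with adjusted p of 0.434 for ribosomal proteins, 0.238 for mesenchymal and 0.436 for MHC genes; in this balanced design the differences themselves are the same with and without the block. Leaving out a line gave 1 to 1092 genes (1 to 457 higher, 0 to 635 lower) and 4 to 12 lists: 1 gene without LN229, 20 without U87MG and 1092 without LN18. Those fits have 1 residual degree of freedom, and only the one without LN18 had an infinite prior, against 4.28 and 5.26. All 96 genes were called without LN18. Over the 3 fits adjusted p ran from 0.00815 to 0.285 for ribosomal proteins (highest without LN229; 0.0872 without LN18), from 0.000703 to 0.966 for mesenchymal and from 0.00193 to 0.479 for MHC genes (both highest without U87MG). CD44 and ABCC1 turned to 0.016 and 0.036 without U87MG, and ABCG2 to -0.046 without LN18.

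With no filter there were 42 genes (42 higher, 0 lower), 9 lists and 5 genes lower by 2-fold in LN18. Cyclic loess gave 38 (38 and 0) and median centring 36 (36 and 0); ABCB5 turned to -0.039 under loess, and ABCG2 to -0.013 under loess and -0.01 under centring. Without a trend 2 genes were lower, and with array weights 8. Testing all probe sets gave 5 (5 higher, 0 lower). That fit adjusted over more tests and also estimated the spread anew over other probe sets, and these changes were not told apart. Camera with an estimated correlation gave 0 lists (0.921 for each of the 4), and fry 0, with 0.676 for small nucleolar and for ribosomal genes, 0.777 for mesenchymal and 0.732 for MHC genes. Protein-coding genes alone gave 0 genes (0 and 0; 1152 at an unadjusted p under 0.05), a mean r between lines of 0.16 in place of 0.40, 0 genes beyond 1.5-fold in 3 lines and 0, 0 and 0 higher by 2-fold in LN229, U87MG and LN18; leaving out short classes gave 0 (0 and 0; 1328 at an unadjusted p under 0.05). Counts between lines stayed within 1.5 times under each alternative run, at 3311 to 3984, 6330 to 8716 and 6145 to 8482. ABCB5, taken from the fit without the filter, has no value of its own for the settings that change the filter. Signal near background limits ABCB5, PROM1 and ABCB1.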

Other observations

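The tests of gene lists between lines and of metallothioneins, and the genes named with them, were chosen after the results were seen. In LN229 the cell cycle lists were higher than in U87MG: 32 of 33 G1/S and DNA replication genes and 35 of 36 G2/M genes passed as higher and 0 as lower (camera adjusted p = 4.39e-19 for each; adjusted p = 0.184 and 0.277 with an estimated correlation). The replication clamp gene PCNA was higher by 1.66 and DTL by 1.61 log2 units. The list of the unfolded protein and amino acid stress response was lower in LN229 than in U87MG, with 23 of 31 genes lower (4.15e-19; adjusted p = 0.184 with an estimated correlation). It was higher in U87MG than in LN18, with 25 of 31 genes higher and 2 lower (2.02e-08; adjusted p = 0.5 with an estimated correlation). HERPUD1 differed by -2.41 and DDIT3 by -2.13 between LN229 and U87MG, and the chaperone gene HSPA5 by 1.94 between U87MG and LN18. U87MG alone was grown in EMEM, so line and medium cannot be told apart in these contrasts.

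LN18 stood apart in other groups. Compared with LN229, ribosomal protein genes were higher in LN18 in 42 of 48 (2.18e-14), NRF2 antioxidant genes in 16 of 22 (2.91e-07) and oxidative phosphorylation genes in 23 of 36 (3.74e-05), each with adjusted p = 0.629 with an estimated correlation. Small nucleolar and small nuclear RNA genes were also higher in LN18, in 25 of 34, with 1 lower. Camera gave that list an adjusted p of 3.31e-07, and 0.629 with an estimated correlation. AKR1B10, an aldo-keto reductase, differed by -3.57 and TXNRD1 by -1.35 for LN229 minus LN18. Of the epithelial-mesenchymal transition and invasion list 20 of 31 genes were higher in LN229 than in LN18 and 5 lower (0.00105; adjusted p = 0.629 with an estimated correlation), with TNC at 4.73 and FN1 at 3.58 but TGFB2 at -2.99. The MHC and antigen processing list did not pass between LN229 and LN18 (camera adjusted p = 0.211), with 7 of 25 members higher and 14 lower in LN229; HLA-DRA differed by 6.16, HLA-B by -1.45 and the immunoproteasome gene PSMB8 by -1.19. Probes for HLA genes lie in polymorphic sequence, so levels between lines can also reflect alleles. Over 39 lists per contrast camera called 13, 18 and 21 and, with an estimated correlation, 0 in each. With 2 residual degrees of freedom the latter has little power, so these lists stay open.

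Metallothionein genes, which bind zinc and copper, formed a hypothesis after MT1CP and MT2A had been seen. Of 13 measured, 9 were lower in the positive fraction of each line, with a median of -0.253 and medians of -0.25, -0.36 and -0.16 in LN229, U87MG and LN18. MT1G differed by -0.36 and MT1CP by -0.56, and 0 of 13 passed the threshold over all genes in limma. As a list, camera gave an adjusted p of 3.11e-09, and adjusted p = 0.908 with an estimated correlation. A shift of the whole family may be present, but the test was chosen on the same data, and the estimated correlation leaves it open.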
